A study of Caenorhabditis elegans with 2 samples.

How the data were processed

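ChIP-seq of GFP-tagged PAG-3 had been performed on 2 biological replicates of late embryos, per the labels. The authors deposited lists of candidate regions for each replicate and for the pooled replicates, described as peaks and background for the IDR procedure, and a list of peaks past an IDR threshold, each in builds ce10 and ce11. The lists carry a signal value and a -log10 q value for every region, both made by the authors, per the labels and the column layout of the deposited lists. The column for p-values held -1 throughout and was not used. Peak caller, aligner, IDR threshold and read depth were not given in the sources used here. The authors' lists were made against a control that is not analysed here. The deposited signal values were used only to rank, match or describe regions. They were averaged over the replicates, or set side by side between replicates and builds, without rescaling. The candidate lists were long and permissive, with 23022 regions in replicate 1, 22971 in replicate 2 and 21336 in the pooled list in ce11, and covered 9.57% of the genome length in the pooled list. The IDR list was identical to the 327 strongest pooled regions in ce11 and to the 471 strongest in ce10, so a limit on the deposited signal value separates peaks from the other candidates. The deposited -log10 q values of the IDR peaks ran from 1.79 to 2.61.

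Genes, transcript starts and sequence were taken from the WBcel235 assembly, which is ce11, and no coordinate was converted between builds. The 6 nuclear chromosomes were used, with 19973 protein-coding genes. A promoter window ran from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start. Regions of different lists were matched by an overlap of at least 1 bp, and the strongest partner was kept. The replicate overlap was tested by 1000 circular shifts within chromosomes. Shares were compared with 2-sided Fisher exact tests against pooled candidates that overlapped no IDR peak, and gene lists against genes with a pooled candidate in the promoter window (6170 genes). Flanking windows for sequence words were centred 500 bp to each side of the summit. Benjamini-Hochberg adjustment was made over the 16 gene lists, over the 2080 words, over the 6 chromosomes and over the 6 location classes. Intervals of shares are 95% Wilson intervals. Intervals and tests treat regions as independent and cover neither the replicates nor the calling of peaks, since 1 group of 2 replicates allows no test between samples.

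The gene lists, the tests and most alternatives were fixed before the data were examined. Named items were the 20 IDR peaks of largest signal value with a candidate in both replicates, named by the nearest transcript start, up to 4 members of each list with the strongest promoter peak, 8 genes fixed beforehand (pag-3, unc-119, mec-3, mec-4, mec-7, ceh-14, flp-10 and nlp-1) and the 3 words of smallest p. List symbols mir-228 and elt-5 were not matched to a protein-coding gene. Alternatives covered the overlap rule, the promoter and sequence windows, backgrounds, a stricter signal limit, the ce10 lists, the loci of pag-3 and unc-119, and each replicate alone. For a replicate alone, its own 327 strongest regions stood in place of the IDR peaks. The comparisons at tRNA and snoRNA genes and in the right end of chromosome V were added after the data were seen. In the logistic model a list with no member carrying a peak was given a p of 1, and shifts of the ce10 lists wrapped at the largest region end of each chromosome. Uniqueness was the share of words of 36 bases, taken along a region, that occur once in the 6 chromosomes.

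The tests were tried on simulated data first. All 20 words planted in 30% of windows were recovered among 2080 words, and none passed with nothing planted. Both sides of that trial were flanks of other candidates, so the difference in GC content between summits and flanks was left out. The trial does not show how many words pass through that difference alone. With peaks given to 30% of the members of a list, 15 of the 16 lists were recovered over 6170 genes, and 2 of 100 random draws gave a list past the threshold. The highest share of any list in the data was 13.3%, for the ribosomal protein genes. The trial therefore does not show how often an enrichment as weak as those seen here would be found. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.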

Results

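The binding of PAG-3 to the genome of Caenorhabditis elegans was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole late embryos. PAG-3 is a zinc-finger transcription factor of the GFI family that acts in the differentiation of neurons, among them the touch receptor and BDU neurons. The worms, of strain OP154, carried an integrated transgene of PAG-3 fused to GFP and FLAG tags, and the chromatin was precipitated with an antibody against GFP. Hermaphrodites were synchronised by egg bleaching and collected 4 hours later. The series held 1 group of 2 biological replicates, so no comparison between conditions could be made, and the questions addressed were where the factor bound and how well the replicates agreed. The lists used here gave no read counts, so the sequencing depth of each replicate was unknown. Signal values are those of the authors' peak lists, and coordinates are in ce11 unless ce10 is named.

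The strongest peak lay on chromosome III from 8043781 to 8044136, in the promoter window of K12H4.5, with a signal value of 685 in the list of peaks that passed the authors' threshold on the irreproducible discovery rate (IDR). It ranked first in each replicate, with a signal value of 339 ± 103 (mean ± SD, n = 2). The next peak, on chromosome III from 3499887 to 3500152, lay in the promoter window of M01F1.9 and had a signal value of 416, or 207 ± 44.4 in the replicates (SD, n = 2). An intergenic peak on chromosome I from 933368 to 933675, nearest to nas-30, had a signal value of 346. An intronic peak on chromosome V from 19643106 to 19643343, nearest to Y43F8C.7, also had 346. The IDR list held 327 peaks in ce11 and 471 in ce10.

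Of the 20 strongest IDR peaks, 9 had their summit in a promoter window, among them those of sre-23 (signal value 285), eel-1 (265), atx-2 (235), T13C5.6 (208), Y62F5A.12 (203), ears-2 (199) and tasp-1 (197). The peak shared by atx-2 and ecps-1 lay on chromosome III from 10461185 to 10461434, 64 bp from the nearest transcript start. The other 11 lay in introns or between genes, and were nearest to nas-30, Y43F8C.7, F55C5.17 (336), W03C9.1 (267), pxn-1 (254), C04A11.5 (240), fbxa-55 (229), str-56 (224), ints-8 (205), col-94 (202) and F15G9.5 (196). A snoRNA gene lay within 100 bp of the summit in 6 of the 20, those nearest to Y43F8C.7, F55C5.17, sre-23, W03C9.1, pxn-1 and str-56. A tRNA gene lay within that distance in 2, those nearest to C04A11.5 and F15G9.5. The intronic peak nearest to ints-8, on chromosome I from 13463880 to 13464031, had its summit within 100 bp of the non-coding RNA gene rpr-1. The small nuclear RNA gene R07E5.16 lay within 100 bp of the col-94 summit. Other non-coding RNA genes within that distance were C14F11.14 at the T13C5.6 peak and F15G9.8 at the F15G9.5 peak. All 20 ranked among the 31 strongest regions of each replicate.

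The regions at K12H4.5, M01F1.9, nas-30, Y43F8C.7 and F55C5.17 were among the 6 strongest of both replicates. Among the 327 strongest regions of replicate 1, 169 (51.7%, 95% Wilson interval 46.3% to 57%) overlapped the 327 strongest of replicate 2 by at least 1 bp, and 168 (51.4%) of those of replicate 2 were shared in turn. Circular shifts of the regions along the chromosomes gave a mean of 0.286% and at most 1.83% (2-sided permutation p = 0.002, the smallest that 1000 shifts can give). Shifted regions ignore promoters, open chromatin and base content, so the overlap was set against arbitrary positions only. The shifts cannot tell shared binding of PAG-3 from enrichment that would recur whatever the tagged protein. All 327 IDR peaks overlapped a candidate region in each replicate, which says little because they come from the pooled replicates and the candidate lists are permissive. Of them, 166 (50.8%) overlapped one of the 327 strongest in both. By the strongest region they overlapped, 19 IDR peaks ranked beyond 1000 in replicate 1 and 14 in replicate 2. The share in common was 58% for the 100 strongest regions of replicate 1 and 41.8% for the 2000 strongest. Spearman's rho of the signal values was 0.311 over 11209 matched candidates and 0.340 over the IDR peaks. These correlations are across regions, which are not independent replicates. Some IDR peaks overlap one another and share their replicate regions, as at eel-1 and rps-24. The IDR peaks are the strongest pooled regions, a restricted range, so their rho is not comparable with that of all matched candidates.

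**Figure D1:**
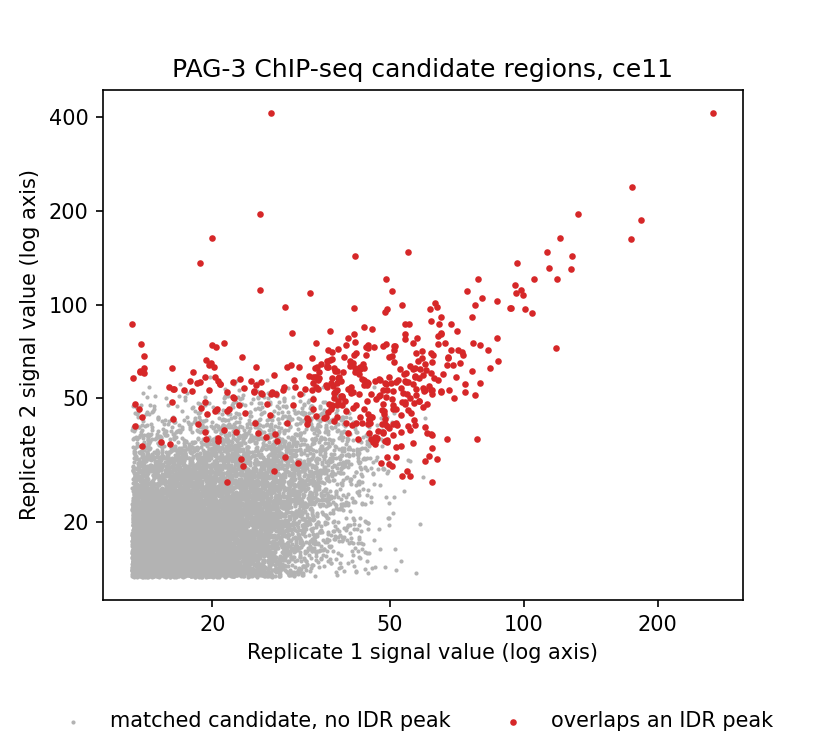
Signal values of the 11209 candidate regions of replicate 1 that overlapped a candidate of replicate 2, each plotted against its strongest partner on log axes. Red points overlap an IDR peak and grey points do not, and the K12H4.5 peak is the red point with the highest value in both replicates; a strong region of replicate 2 can be the partner of more than 1 region of replicate 1.

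Peaks of PAG-3 lay near the starts of protein-coding genes more often than the remaining candidates. The summit was in a promoter window in 168 of the 327 IDR peaks (51.4%, 46% to 56.7%) and in 6502 of 20889 other pooled candidates (31.1%, 30.5% to 31.8%), an odds ratio of 2.34 (1.88 to 2.91, 2-sided Fisher exact p = 6.31e-14). These windows made up 26.1% of the genome. Promoter windows of 222 genes held an IDR summit, and 57 of the 168 peaks lay in the windows of more than 1 gene. Among classes described after the values were seen, coding exons held 3.98% of IDR summits against 22.2% of the others (adjusted p = 1.79e-19, Fisher exact test), and introns held 22.3% against 24.1% (adjusted p = 0.569).

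Genes for small non-coding RNAs, a class chosen after the values were seen, were frequent among the IDR peaks. A tRNA gene lay within 100 bp of the summit in 56 IDR peaks (17.1%, 13.4% to 21.6%) and in 191 of the 20889 other candidates (0.914%). A snoRNA gene, whose product guides the modification of other RNAs, lay within that distance in 29 IDR peaks (8.87%, 6.25% to 12.4%) and 57 other candidates (0.273%). For both kinds together the odds ratio was 29.2 (22.2 to 38.6, 2-sided Fisher exact p = 2.80e-80), and at a distance of 500 bp it was 19.4. Their share was 20.2% among the 327 strongest regions of replicate 1 and 23.2% among those of replicate 2.

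**Figure D2:**
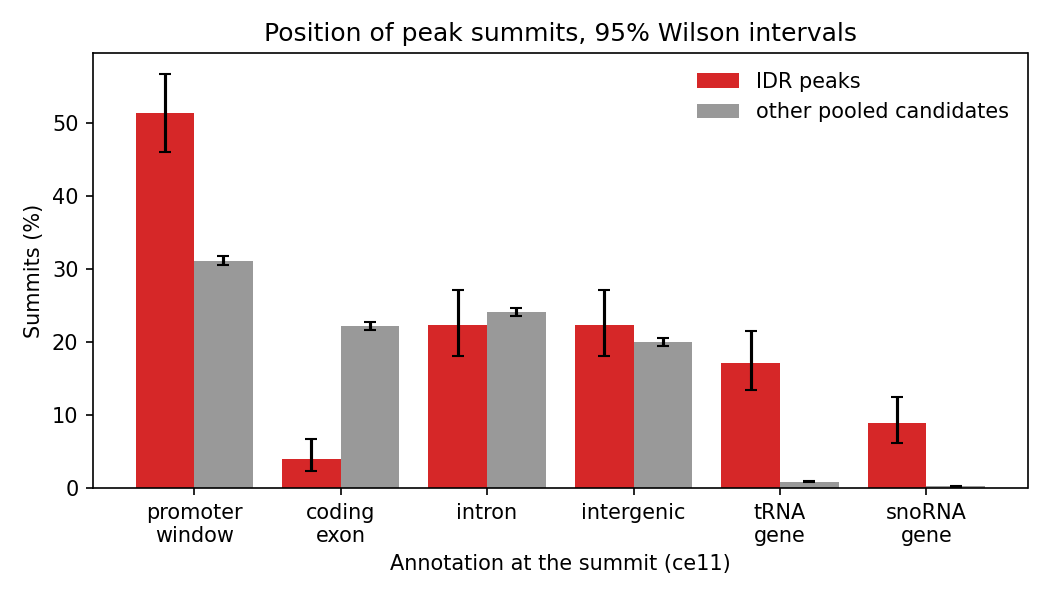
Share of peak summits, in percent, by the annotation at the summit, for the 327 IDR peaks (red) and the 20889 other pooled candidates (grey), with 95% Wilson intervals as error bars. The first 4 classes exclude one another, and the last 2, genes within 100 bp of the summit, overlap them; the promoter share is 51.4% against 31.1% and the tRNA share 17.1% against 0.914%.

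The X chromosome carried 73 of the 327 IDR peaks (22.3%, 18.1% to 27.1%), against 16.3% of the other candidates and 17.7% of the genome length. The odds ratio was 1.48 (1.14 to 1.92, 2-sided Fisher exact p = 0.00517, adjusted p = 0.0310 over the 6 chromosomes). Chromosome V carried 82 of the 327 peaks and 4095 of the 20889 other candidates, an odds ratio of 1.37 (1.07 to 1.77, Fisher exact p = 0.0170, adjusted p = 0.0509). Chromosome I carried 51 peaks, chromosome III 42, chromosome II 41 and chromosome IV 38. Of the peaks at tRNA genes, 33 of 56 were on the X chromosome, which holds 45.1% of the annotated tRNA genes. Without peaks and candidates at tRNA or snoRNA genes, an alternative added after the data were seen, the X share was 16.5% against 16.1% (odds ratio 1.03, Fisher exact p = 0.860), and from replicate 1 alone the odds ratio was 1.13 (p = 0.408).

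With each chromosome divided into 5 equal parts, the right end of chromosome V, from 16739345 to 20924180, held 41 IDR peaks (12.5%, against 6.84% of the other candidates). This region was chosen after the values were seen, and its odds ratio was 1.95 (1.40 to 2.72, 2-sided Fisher exact p = 0.000244). Among its strongest peaks were those nearest to Y43F8C.7, srw-32 (signal value 127, intergenic) and Y59A8B.24 (124, intergenic). The next highest of the other 29 parts, part 4 of the X chromosome, held 17. The region held 64 of the 327 strongest regions of replicate 1 and 38 of those of replicate 2. The odds ratio was 3.40 from replicate 1 alone, 1.78 from replicate 2 alone and 2.48 with the ce10 lists. Among the stronger part of the IDR peaks, 163 in number, it was 1.38 (Fisher exact p = 0.215).

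**Figure D3:**
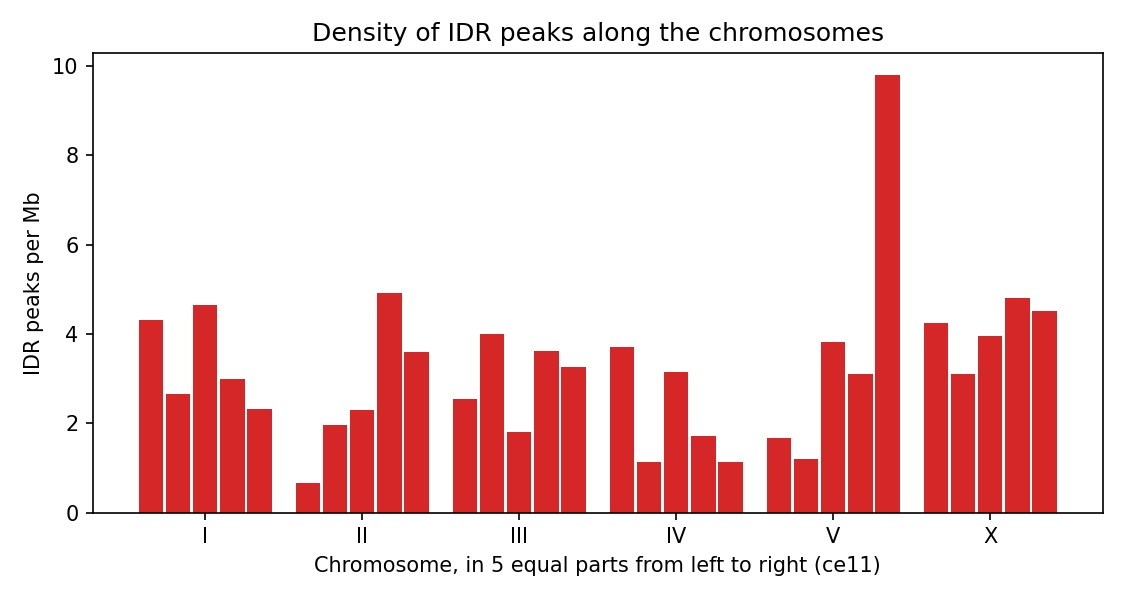
IDR peaks per Mb (vertical axis) in each of 5 equal parts of the 6 chromosomes, from left to right (horizontal axis, ce11). The right end of chromosome V stands at 9.80 peaks per Mb, and the next highest part, on chromosome II, at 4.91.

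No gene list fixed before the data were examined passed the test, and 3 genes of the neuronal lists had an IDR peak at the promoter. The touch receptor and BDU neuron genes had no member with an IDR peak in the promoter window among 13 with a candidate region there. The same held for the dense-core vesicle genes (0 of 13), the neuropeptide precursor genes (0 of 33), the neuronal identity transcription factors (0 of 32) and the ciliary and sensory genes (0 of 14). Over the background genes outside a list about 3.6% carried a peak, so lists of this size can hold none by chance. The 8 neuronal lists joined, a set formed after the values were seen, had a peak at 3 of 159 genes (1.89%) against 3.64% of the other genes (odds ratio 0.509, 0.161 to 1.61, 2-sided Fisher exact p = 0.382). Single members carried a peak in the pan-neuronal synaptic list (cla-1, which encodes an active zone protein, signal value 87.9), the neurotransmitter list (egl-30, a G protein alpha subunit, 90.4) and the axon guidance list (unc-115, 98.4). Outside neurons, single members were lin-35, the worm retinoblastoma homologue (158), in the cell cycle and cell death list and mex-1 (139) in the germline list. No peak was found at promoters of the body muscle (0 of 31), intestine (0 of 8), epidermis and cuticle (0 of 18), pharynx (0 of 10) and glial (0 of 4) lists. Assigned instead to the gene of the nearest transcript start, peaks fell at 1 of 19 touch receptor and BDU genes. They fell at 3 of 39 pan-neuronal synaptic genes (7.69%, against 3.02% of other genes), and no list passed. The dense-core vesicle genes then had 1 of 20, the neuropeptide precursor genes 2 of 58 and the identity transcription factors 1 of 60. The ciliary and sensory genes had 0 of 26.

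Ribosomal protein genes had the most members with an IDR peak at the promoter. An IDR peak lay in the promoter window of 6 of 45 (13.3%), against 3.53% of the other 6125 genes, an odds ratio of 4.21 (1.76 to 10.0). The adjusted p was 0.0816 over the 16 lists (2-sided Fisher exact test, unadjusted p = 0.00510), so the list did not pass, and it was the only list with an unadjusted p below 0.05. The strongest members were rps-24 (signal value 195), rpl-3 (156), rpl-15 (155) and rpl-43 (122), and the remaining members were rpl-20 and rps-28, named after their values were seen. With all protein-coding genes as background the adjusted p was 0.00322, and with each peak assigned to the gene of the nearest transcript start it was 0.913 (odds ratio 2.74).

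None of the 8 genes fixed beforehand (pag-3, unc-119, mec-3, mec-4, mec-7, ceh-14, flp-10 and nlp-1) had an IDR peak at the promoter. At pag-3 itself, on chromosome X from 14950752 to 14954648, no candidate lay in the promoter window or gene body, and the nearest IDR peak was 109596 bp away. The rescue marker unc-119, on chromosome III from 10902641 to 10908935, had 2 candidates in its promoter window, the stronger ranked 13952 with a signal value of 29.0. The homeobox gene ceh-14 had 1 candidate, ranked 8665 (signal value 34.4). The promoter windows of mec-3, mec-4, mec-7, flp-10 and nlp-1, of which the first 3 act in touch receptor neurons and the last 2 encode neuropeptides, held none. Within 20 kb of pag-3 there were 2 pooled candidates, the 2.87th percentile of all protein-coding genes by density, but counting error on so few allows percentiles from 0.776 to 37.5. Within 50 kb there were 17, the 32.8th percentile, so the locus was not shown to be poor in candidates. Within 20 kb of unc-119 there were 14, the 83.5th percentile (37.8 to 98.8).

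The sequence under the summits was richer in G and C than the flanks and did not hold the core of the GFI binding site more often than they did. The word AATCAC, on either strand, occurred in 12 of 327 summit windows of 101 bp (3.67%, 2.11% to 6.30%) and in 27 of 654 flanking windows (4.13%, 2.85% to 5.94%). The odds ratio was 0.885 (0.442 to 1.77, 2-sided Fisher exact p = 0.863). Mean GC content was 50% ± 8.43 (SD over windows, n = 327) at summits, 37% ± 8.46 in the flanks and 42.4% ± 10.1 at the other candidates. The median odds ratio over the 60 words of the same base composition as AATCAC, itself included, was 0.616, with 16 words above AATCAC. Words of this composition thus tended to be less frequent at summits, so the comparison with the flanks cannot exclude an excess beyond base content. The comparison with words of the same composition was added after the data were seen and carries no test.

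Of 2080 words of 6 bases, 339 were more frequent at summits than in the flanks and 235 less frequent at an adjusted p below 0.05 (Fisher exact test). The 3 words of smallest p were all less frequent at summits. CTGAAA, whose reverse complement TTTCAG resembles the 3' splice site of worm introns, occurred in 3.98% of summit windows against 23.4% of flanks (odds ratio 0.136, Fisher exact adjusted p = 1.34e-13). AAAAAT occurred in 18% against 43.4% (Fisher exact adjusted p = 9.35e-13) and TGAAAA in 10.7% against 32.9% (adjusted p = 2.38e-12). Among the more frequent words, named after their values were seen, AGAGAG occurred in 16.2% against 3.52% and GCGCGC in 8.87% against 0.612%. The words more frequent at summits held 4.32 G or C bases on average and the less frequent ones 1.45.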

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

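The alternatives that left out tRNA and snoRNA genes or the right end of chromosome V, and all those of the tRNA and snoRNA shares and of that region, were chosen after the data were seen. Under the alternatives fixed beforehand, the replicate overlap (45.6% to 56.4%) and the promoter share (odds ratio 1.65 to 2.77) kept their direction and side of the threshold. The IDR peaks numbered 471 in ce10 against 327, and the percentile of pag-3 was 32.8 with 50 kb on each side against 2.87. The X share lost its call in the stronger part of the peaks (odds ratio 1.36, Fisher exact p = 0.135) and without tRNA and snoRNA genes (1.03). From a single replicate its odds ratio was 1.13 to 1.42, and the call was lost without replicate 2. The number of gene lists past the threshold was 0 to 1 with a replicate left out, and 1 with the wider promoter window, with all protein-coding genes as background, with upstream intergenic length in a logistic model and without tRNA and snoRNA genes. That list was the ribosomal protein genes each time (adjusted p from 3.02e-05 to 0.913 over all alternatives, the highest with assignment to the nearest transcript start). The logistic model also ran over all protein-coding genes and so shares that change of background. Its odds ratio for this list was 7.79, against 7.81 with that background and no intergenic length. AATCAC stayed uncalled, with an odds ratio from 0.179 (Fisher exact p = 0.0711, windows of 25 bp each side) to 1.13 (p = 0.830, without tRNA and snoRNA genes, where the direction turned). It was 0.655 with 100 bp each side. For the longer word AATCACWGC the odds ratio was 0.665, with an interval of 0.0270 to 16.4 that is too wide to decide. The word AAATCA was less frequent at summits (odds ratio 0.481, Fisher exact p = 0.00136). AAATCA is rich in A and T, as were the words less frequent at summits (1.45 G or C bases on average). It was not compared with words of its own composition, so its lower share cannot be told apart from base content. The words past the threshold numbered 257 in the stronger part of the peaks and 365 against other candidates. Spearman's rho was 0.381 for summits within 100 bp and 0.340 over IDR peaks. The excess in the right end of chromosome V lost its call in the stronger part of the peaks (odds ratio 1.38). The odds ratio at tRNA and snoRNA genes was 19.6 to 24.4 from a single replicate, 19.4 at 500 bp, 27.1 at 0 bp and 41.2 in the stronger part of the peaks. Apart from the X share without tRNA and snoRNA genes, taken up among the other observations, the cause was not tested. Unknown depth limits how far the absence of a peak can be read.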

Other observations

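All of the tests below were chosen after the patterns they bear on were seen. What the test on GC content would show was written down before its own result was seen, and for the others afterwards. With 1 group in the design no explanation by a difference between conditions was tested.

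IDR peaks lay at tRNA and snoRNA genes far more often than other candidates did. Their joint median of unique words, 89.2%, decided nothing, and the kinds were then taken apart. Peak regions at snoRNA genes held a median of 100% words of 36 bases that occur once in the genome, which argues against reads shared between gene copies there. At tRNA genes the median was 88.0% (quartiles 86.4% to 89.2%), between the bounds set for the test. Words were counted over whole regions, of median width 450 bp among the IDR peaks. A repeat confined to a gene much shorter than the region leaves most words unique, so the lower bound could hardly be reached. The test therefore cannot tell shared reads from binding at those 56 peaks. GC content does not account for the pattern as a whole, because with other candidates weighted to the GC content of the peaks the odds ratio was 20.5 (bootstrap interval 15.2 to 26.9). Strong enrichment of highly transcribed or open chromatin in the precipitation, whatever the tagged protein, stays open, since the control was not analysed here. It stays open for the other peaks too, those at ribosomal protein genes among them.

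The higher share of peaks on the X chromosome may rest on its tRNA genes. Without peaks and candidates at tRNA and snoRNA genes the odds ratio was 1.03 (0.732 to 1.45), below the lower bound of 1.14 for all peaks. No peak at a snoRNA gene was on the X chromosome.

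The dense peaks in the right end of chromosome V held a median of 100% unique words, which argues against exact repeats within the assembly. Diverged copies, or copies missing from the assembly, are not covered by that test. Promoter windows held 29.3% of these peaks against 54.5% of the other peaks (2-sided Fisher exact p = 0.00261), so most were not at promoters. Most other candidates of the region, 1111 of 1429, lay outside promoter windows too, so a low promoter share is not particular to its peaks. Weak candidates outside promoters were also dense there, at 265 per Mb against a median of 139 and a highest value of 212 in the other 29 parts. A candidate explanation is a broad rise of enrichment over the region, as extra DNA copies in these worms relative to the control would give. Read depth over the region in the precipitated and control libraries, not analysed here, would test it. The excess was larger from replicate 1 alone (odds ratio 3.40) than from replicate 2 alone (1.78). Extra copies common to both replicates do not by themselves account for that difference.

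The signal values of the pooled regions were nearly the same in both builds, with a largest value of 685 in each, while the weakest IDR peak had 84.0 in ce11 and 76.3 in ce10.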
